A study of Oryza sativa with 4 samples.

How the data were processed

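RNA of whole seedlings at the 3-leaf stage was isolated from 3 replicates per line and time and pooled in equal amounts before library preparation. The RNA input was 3 µg, per the labels' protocols. Each of the 4 groups therefore has 1 library, and p-values between groups were not computed. A fit of line and time without their interaction would leave 1 residual degree of freedom, which takes the difference of responses as error. It was not planned and was not run. Libraries were made with a NEBNext Ultra RNA kit and sequenced on an Illumina HiSeq, per the labels' protocols and design text. The temperature and the hour of sampling are not given in the sources used here. The authors deposited 1 table of FPKM values, per the labels and the table itself. HTSeq 0.6.1 is named in the submitters' processing notes; the aligner, the genome build and the annotation are not given in the sources used here. Columns were matched to samples by their titles.

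The deposited FPKM values keep full precision, so their steps were examined. An FPKM is a whole number of reads divided by a gene length and a library total. The ratio of low values between libraries gave the relative totals, and the spacing of the inverse steps gave the absolute totals as whole numbers in all 4 libraries, from 10580163 to 11800685. The smallest length up to 30000 that made all libraries' reads whole, within a tolerance of 1e-07, was found for 34043 of the 34043 identifiers above 0, which is 100% of them. Reads and length can share a factor, so these reads are the smallest that fit; their sum was 97.6% to 97.7% of each total. In a simulated table with 32780 identifiers above 0, all 4 totals were recovered exactly, 97.5% of reads were recovered, and no identifier got more reads than were drawn. Lengths of BGIOSGA identifiers were multiples of 3 in 98.8% of cases and are called coding lengths. Recovered reads served for depth, counting intervals and added filters, and no count model was run, since no group has a replicate. Counting intervals are exact Clopper-Pearson intervals at 95% on the reads of 2 libraries. They cover counting error only, because PCR reads are not independent molecules, and where a factor was lost they are too wide. A value of 0 was set at 3 reads per library to give a ratio, which leaves out the counting error of the other library.

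Before the data were examined, the size rule, the alternatives, the rule for named items and the gene lists were fixed. An identifier passed the rule with a log2((FPKM + 1)/(FPKM + 1)) of at least 1 in size and FPKM of at least 1 in either library. This ratio understates the difference of low values, and ratios given with a counting interval have no pseudocount. Data for 36 h over 0 h in DC90 were simulated on 34043 identifiers, with changes given only to BGIOSGA identifiers with FPKM of at least 5 before the change. A true 4-fold or 8-fold difference was called in 100% of 50 such identifiers each, a 2-fold difference in 20% and a 1.5-fold difference in 0%. Changes from lower levels were not simulated. Calls were also given to 134 unchanged BGIOSGA and 1180 unchanged EPlOING identifiers. The rule for named items takes the 2 highest and 2 lowest ratios per comparison with FPKM of at least 10 in the higher library when identifiers carry no names. The parts of that rule that would name list members and genes of a stretch were not used, for the same reason. Of the table's identifiers, 0 were found in the reference gene table, which pairs RefSeq genes of assembly ASM3414082v1 with symbols, and 0 of the 118 members of the 14 lists fixed by identifier, root markers included, were in the data table. The 14 lists by identifier (cold regulators, chilling tolerance loci, abscisic acid, dehydrins, trehalose and galactinol, antioxidant enzymes, chlorophyll synthesis, chlorophyll breakdown, circadian clock, jasmonate, gibberellin, defence, reference genes and root markers) and the 28 lists by description therefore gave no value.

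For comparisons of 2 libraries, counts expected from counting error were the means of 100 Poisson draws with 1 shared rate per identifier and the recovered lengths and totals. For the difference of responses, the 100 draws kept each line's mean level and gave both lines 1 shared response. Line differences were planned to be counted along the chromosomes. Since positions could not be assigned, the order of identifier numbers was used instead, a choice made after the identifiers were seen. For this, BGIOSGA identifiers past the rule in the same direction at both times were counted in windows of 50 in order of identifier number, and the order was shuffled 1000 times; simulated flags with 2 planted stretches gave both and no other. Stretches set at 0 h alone were read at 36 h without the identifiers past the rule at 0 h, and were compared with 1000 random placements along the same order. The alternatives were a pseudocount of 0.1 without a low-value filter, FPKM of at least 5, median-of-ratios factors, rescaling to equal FPKM sums, a 4-fold threshold and windows of 100. Added after the data were seen were filters on 20 or 100 reads and thinning to the smallest library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.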

Results

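Whole rice seedlings of 2 lines were sampled before chilling (0 h) and after 36 h of chilling, and their RNA was sequenced. DC90 is a chilling-tolerant chromosome substitution line, that is, a line carrying donor chromosome segments in the background of a recurrent parent. The line 9311, also called YD6, is that chilling-sensitive recurrent parent. Each of the 4 combinations of line and time is represented by 1 library, made from RNA of 3 replicates mixed in equal amounts. No comparison below therefore has a replicate check within a group, no test between conditions was run, and "higher" and "lower" describe these 4 libraries. None of the 4 libraries comes from unchilled seedlings at 36 h. Changes with seedling age or time of day therefore cannot be told apart from effects of chilling, also where both lines changed alike. "Response" below means the ratio of 36 h over 0 h within a line. The values are the authors' FPKM (fragments per kilobase of gene length, scaled to the library total) for 88509 identifiers, of which 40745 begin with BGIOSGA and 47764 with EPlOING. The library totals behind the values, recovered from their step sizes, were 11709642 reads for DC90 at 0 h, 10580163 for DC90 at 36 h, 11800685 for 9311 at 0 h and 10901043 for 9311 at 36 h. BGIOSGA identifiers with FPKM of at least 1 in any library numbered 24192, with a median coding length of 1026 bases and a median of 211 reads in their deepest library. The corresponding 3521 EPlOING identifiers had a median recovered length of 69 bases and a median of 3 reads, and 89.7% of them stayed under 20 reads in every library. The sources used here do not pair these identifiers with gene names or positions, so groups of genes by function are not described.

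After 36 h of chilling, 33.7% of the identifiers measured in DC90 differed at least 2-fold from the level before chilling. Of 26150 identifiers with FPKM of at least 1 at either time, 4673 were higher and 4150 lower on the log2(FPKM + 1) scale. Among BGIOSGA identifiers, 3374 were higher and 3575 lower, together 29.8% of the 23341 measured. Of these, 767 and 817 differed at least 4-fold. With a pseudocount of 0.1 and no low-value filter, 5507 were higher and 6002 lower. The highest ratio belonged to BGIOSGA007022, which went from an FPKM of 1.39 to 507, a 365-fold difference with a 95% counting interval of 259 to 534. EPlOING00000038693 went from 1.59, resting on 3 reads, to 513, a ratio of 322 with an interval of 109.97 to 1567. The lowest ratio belonged to BGIOSGA014277, at 446 before and 1.81 after chilling, 246-fold lower with an interval of 105 to 759.8. BGIOSGA004922 was 227-fold lower, at 131 before and 0.577 after. Poisson draws in which the 2 libraries shared 1 rate per identifier placed on average 133 BGIOSGA identifiers and 947 EPlOING identifiers past the rule, against the observed 6949 and 1874. Rescaling the libraries to equal FPKM sums moved the median log2 ratio of well-measured identifiers by 0.10, and BGIOSGA identifiers higher at 36 h then made up 55.5% of those past the rule in place of 48.6%, so which direction was more frequent depended on the scaling.

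In 9311, 5036 identifiers were higher and 4987 lower after chilling, together 37.9% of the 26446 measured. Of the BGIOSGA identifiers 3788 were higher and 4293 lower, together 34.3% of the 23563 measured, with 1069 and 995 beyond 4-fold. A pseudocount of 0.1 without a low-value filter gave 5714 higher and 6903 lower. BGIOSGA033960 was at 0.214, a single read, before chilling and at 436, from 1883 reads, after it, a ratio of 2038 with an interval of 365 to 80555. In DC90 the same identifier was listed at 0 before chilling and at 191 after it. BGIOSGA007022, the highest in DC90, was also among the highest here, at 1.12 before and 465 after chilling, a ratio of 416 with an interval of 283 to 636. BGIOSGA013921 was 169-fold lower, from 334 to 1.98, with an interval of 104 to 295. BGIOSGA013669 was 180.2-fold lower, from 273 to 1.51, with an interval of 97.8 to 376. The draws without a difference placed 134 BGIOSGA identifiers past the rule, against the observed 8081.

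**Figure D1:**
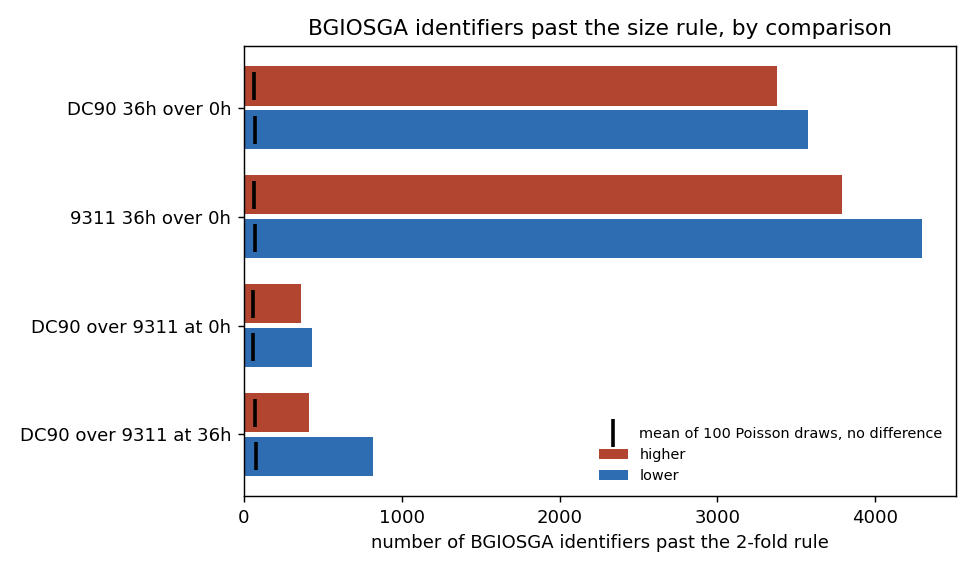
Number of BGIOSGA identifiers (x axis) at least 2-fold higher (red) or lower (blue) on the log2(FPKM + 1) scale in each comparison of 2 single libraries (y axis). Black ticks give the mean of 100 Poisson draws without a difference. The bars for 36 h against 0 h, from 3374 to 4293, are longer than those between lines at one time, from 364 to 817.

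The responses of both lines went largely in the same direction. Of the 3374 BGIOSGA identifiers higher in DC90 after chilling, 2512 were also higher in 9311, where independent lists would share 528. Of the 3575 lower in DC90, 2782 were also lower in 9311, against 634 for independent lists. The rule was passed in opposite directions by 14 BGIOSGA identifiers. The 2 responses share no library. Across 14185 BGIOSGA identifiers with FPKM of at least 5 in all 4 libraries, Pearson's r between the log2 ratios was 0.89 and Spearman's rho 0.88; this is a correlation across genes, which are not independent replicates. The response was somewhat larger in 9311, with an SD of log2 ratios of 1.03 against 0.94 in DC90 and a principal-axis slope of 1.11 for 9311 on DC90. Identifiers chosen as higher in DC90 had a median log2 ratio of 1.44 there and 1.46 in 9311, whereas those chosen as higher in 9311 had 1.53 there and 1.28 in DC90. For identifiers chosen as lower the medians were -1.46 in DC90 and -1.52 in 9311 when chosen in DC90, and -1.51 in 9311 and -1.23 in DC90 when chosen in 9311. With 1 pooled library per line and time, a difference of this size between lines cannot be set against the spread between pools.

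**Figure D2:**
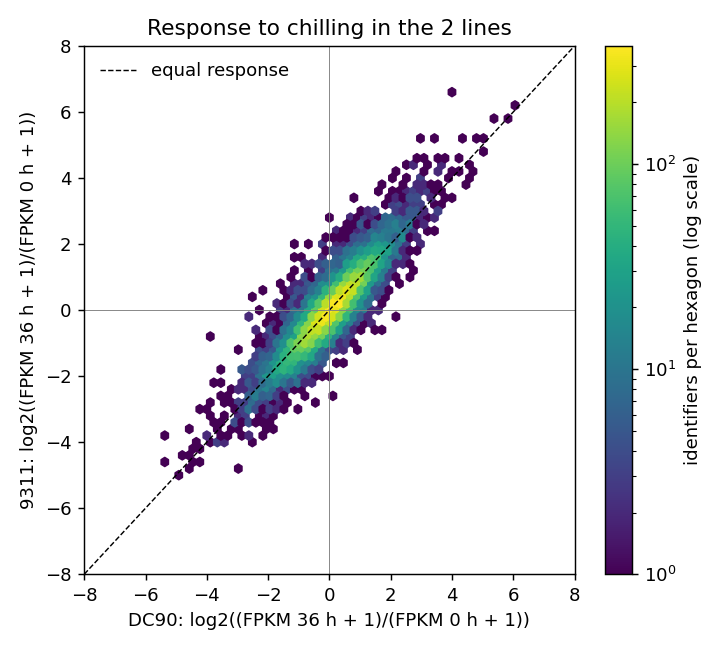
Log2 ratio of 36 h over 0 h in DC90 (x axis) against that in 9311 (y axis), with 1 added to each FPKM, for the 14185 BGIOSGA identifiers with FPKM of at least 5 in all 4 libraries. The colour gives the number of identifiers per hexagon on a log scale, and the cloud follows the dashed line of equal response with a principal-axis slope of 1.11.

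Before chilling, fewer identifiers differed between the lines than between times in either line. Of 22919 BGIOSGA identifiers with FPKM of at least 1 in either line, 364 were at least 2-fold higher and 429 lower in DC90 than in 9311, which is 3.46%. These counts depended on the treatment of low values, at 1708 and 2092 with a pseudocount of 0.1 and no low-value filter and at 241 and 249 with FPKM of at least 5. Beyond 4-fold there were 61 and 75. BGIOSGA040274 was at 1114 in DC90 and at 0.406, from 2 reads, in 9311, a ratio of 2740.1 with an interval of 758 to 22632. BGIOSGA013100 was at 165 in DC90 and at 0.118, from 1 read, in 9311, a ratio of 1403 with an interval of 251 to 55448. BGIOSGA037365 was at 0.181, from 1 read, in DC90 and at 149, from 827 reads, in 9311, where the ratio of 9311 to DC90 was 821 with an interval of 147 to 32451. EPlOING00000025927, with a recovered length of 35 bases, was listed at 0 in DC90 and at 159.8, from 66 reads, in 9311. It was 21.8-fold lower in DC90 when DC90 is set at 3 reads, and the counting interval of the ratio of 9311 to DC90 began at 17.3. For identifiers with FPKM of at least 5 in both libraries, the SD of the log2 ratio between lines was 0.32, against 0.94 between times in DC90. With EPlOING identifiers included, 925 were higher and 1122 lower. EPlOING identifiers made up 61.3% of these, and draws without a difference gave 828 of their 1254. Among BGIOSGA identifiers with at least 20 reads in the higher library, a condition set after the data were seen, 260 were higher and 314 lower, together 574 against 11.1 in the draws.

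After 36 h of chilling, more BGIOSGA identifiers were lower in DC90 than higher. The rule was passed by 412 higher and 817 lower identifiers of 22603 measured, or 5.44%, and the share that was higher was 33.5%, against 45.9% at 0 h. Both counts were above the 364 and 429 at 0 h, the lower ones by more. The rise of the higher count depended on the setting, since it went from 241 at 0 h to 228 at 36 h with FPKM of at least 5. With median-of-ratios factors it went from 354 to 339, while it rose under the other settings. The lower count was above that at 0 h under all settings. The contrast in shares was absent where low values were let in, at 45.6% at 36 h and 44.9% at 0 h with a pseudocount of 0.1 and no low-value filter. It was wider where low values were removed, at 28.9% against 49.2% with FPKM of at least 5. With median-of-ratios factors the shares were 26.5% at 36 h and 44.4% at 0 h. The share was lower at 36 h under the other settings too. The counts at 36 h were 2097 higher and 2503 lower with a pseudocount of 0.1 and no low-value filter. They were 228 and 562 with FPKM of at least 5 and 68 and 123 beyond 4-fold. The same identifiers as at 0 h stood at both ends. BGIOSGA040274 was at 993 in DC90 and 1.54, from 7 reads, in 9311, a ratio of 645 with an interval of 313 to 1605. BGIOSGA013100 was at 175 in DC90 and 0.127, from 1 read, in 9311. BGIOSGA037365 was at 0.401, from 2 reads, in DC90 and 189 in 9311. EPlOING00000025927 was again listed at 0 in DC90 and stood at 97.0 in 9311. The SD of the log2 ratio between lines was 0.39, and the draws without a difference gave 147 BGIOSGA identifiers. The count with EPlOING identifiers included was 1198 higher and 1588 lower. With at least 20 reads, 280 BGIOSGA identifiers were higher and 634 lower.

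Few of the line differences were present at both times. Of the BGIOSGA identifiers higher in DC90 at 0 h, 97 of 364 were also higher at 36 h, and 132 of the 429 lower ones were also lower at 36 h. Independent lists would share 6.20 and 14.5. Across the 14185 identifiers with FPKM of at least 5 in all libraries, the line ratios at 0 h and at 36 h had a Pearson's r of 0.04 and a Spearman's rho of -0.03 across genes. That filter leaves out identifiers with low FPKM in either line, such as BGIOSGA040274, BGIOSGA013100 and BGIOSGA037365, which differed at both times. Over all 24192 BGIOSGA identifiers with FPKM of at least 1 in any library, r was 0.33 and rho 0.07. Listed at 0 in both DC90 libraries with FPKM of at least 5 in both 9311 libraries were 14 BGIOSGA identifiers, and 18 showed the opposite.

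The difference between the 2 responses, which the design of line by time addresses, was at least 2-fold upward in DC90 for 906 and downward for 1091 of 24192 BGIOSGA identifiers. With a pseudocount of 0.1 and no low-value filter the counts were 3458 and 3197, with FPKM of at least 5 they were 583 and 795, and beyond 4-fold 53 and 132. In 588 of the 906 and 688 of the 1091, the response was the smaller one in DC90. The first set had a median log2 ratio of 0.23 in DC90 and -1.11 in 9311, and the second had -0.20 in DC90 and 1.198 in 9311. Of the first set 347 were lower past the rule in 9311 alone and 179 were higher in DC90 alone. Of the second, 393 were higher in 9311 alone and 254 lower in DC90 alone. Draws in which both lines kept their own mean level but shared 1 response gave 760.4 BGIOSGA identifiers in all, against the observed 1997. Where at least 20 reads were required, they gave 329 against 1582. A shared response from unlike levels can pass the rule once 1 is added to each FPKM. The drawn counts therefore hold more than counting error, and the observed ones can include such identifiers. The extreme values rested on few reads: EPlOING00000043315 at 5.79 and EPlOING00000033746 at 5.67 above, and EPlOING00000025841 at -6.18 and EPlOING00000044378 at -5.93 below, had at most 11 reads in any library. Over all identifiers the counts were 2042 and 2048. Of the BGIOSGA identifiers 45.4% were in the upward set, and 51.0% after rescaling to equal FPKM sums, so that which direction was more frequent depended on the scaling as well as on the treatment of low values.

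The 229 BGIOSGA identifiers that differed between lines in the same direction at both times lay partly close together in identifier number. DC90 is a substitution line, and the comparison asked whether its differences from 9311 gather in stretches. In windows of 50 identifiers with FPKM of at least 1, taken in order of their number, the fullest window held 13 of them, and the fullest in 1000 shuffles of the order held 6. Windows fuller than that covered 7 stretches, which held 745 identifiers, or 3.08%, and 112 of the 229. The stretches ran from number 10224 to 10354, 12710 to 12820, 12941 to 13206, 36041 to 36545, 37025 to 37085, 37124 to 37212 and 37288 to 37534. Between 14.1% and 16.9% of the identifiers in each stretch passed the rule, against 0.499% elsewhere, a contrast that partly follows from setting the stretches by these identifiers. Within them 47 identifiers were higher and 65 lower in DC90. For EPlOING identifiers, those shared between times numbered 110 higher and 142 lower, against 125 and 152 for independent lists, so their placement is not described. BGIOSGA013100 and BGIOSGA037365 lay in stretches and BGIOSGA040274 did not. The order here is that of the identifier numbers, and chromosome positions were not used here.

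**Figure D3:**
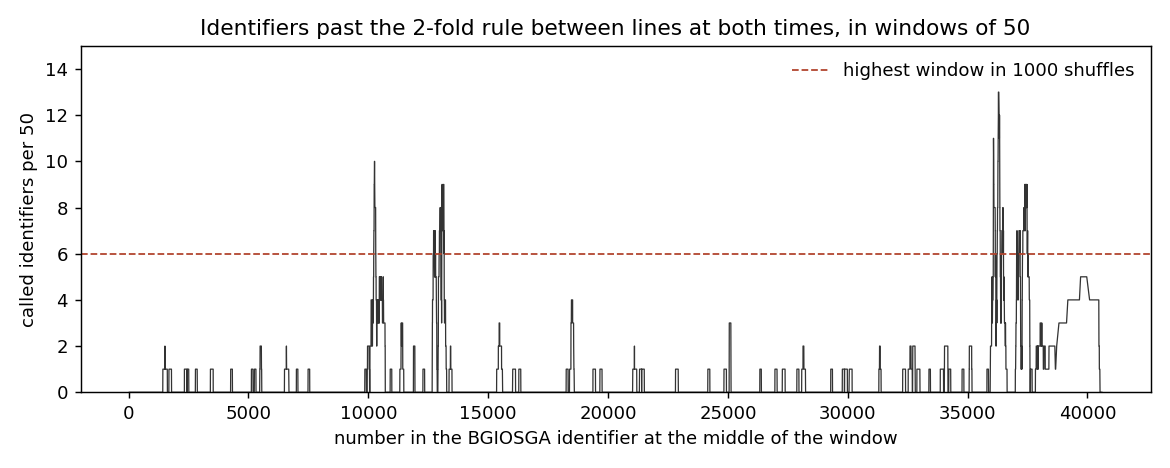
Number of BGIOSGA identifiers at least 2-fold different between lines in the same direction at 0 h and 36 h (y axis) in windows of 50 measured identifiers, placed at the identifier number in the middle of each window (x axis). The dashed line marks 6, the fullest window in 1000 shuffles, and the windows rise above it in the 7 stretches, up to 13.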

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

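The tests of placement by chance, of lost mapping and of a lasting line difference, and the filters on reads, were chosen after the data were seen.

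After 36 h, 201 identifiers were at least 2-fold higher in one line and at least 2-fold lower in the other, and this difference between lines was not tested because each has 1 library per time. Of these, 187 were EPlOING identifiers and 14 BGIOSGA identifiers, 6 of which had at least 20 reads in some library. Among the named items, EPlOING00000043315 with a difference of responses of 5.79, EPlOING00000033746 with 5.67 and EPlOING00000044378 with -5.93 also went opposite ways, each on 7 reads or fewer per library.

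Identifiers past the 2-fold rule after chilling were more numerous in 9311 than in DC90 by a ratio of 1.14. Thinning all libraries to the same total left the ratio at 1.14. At 0 h the totals were 11709642 reads in DC90 and 11800685 in 9311. At 36 h they were 10580163 in DC90 and 10901043 in 9311. Totals this close leave thinning little to change, so it cannot decide whether they were a cause. Median-of-ratios factors gave 1.15. Among BGIOSGA identifiers alone the ratio was 1.16, and it was 1.19 for those with at least 100 reads. Over all identifiers the ratio was 1.09 with a pseudocount of 0.1 and no filter on low values. A difference between pools of plants, and a line difference in the response, both stay open, since neither can be tested with 1 pool per line and time.

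BGIOSGA identifiers that differ between lines at both times lay partly close together in identifier number. The fullest window held 13 identifiers where 1000 shuffles reached 6, which argues against independent placement of single identifiers. The shuffles moved each identifier by itself, so they cannot address neighbours in number that vary together for other reasons. Among identifiers with at least 100 reads the fullest window held 8, where shuffles reached 5. This argues against counting error as the only cause. Loss of DC90 reads in mapping, as the only cause, would make nearly all such identifiers in the stretches lower in DC90, but 58.0% were lower (exact binomial interval 48.3% to 67.3%). That interval takes identifiers as independent, which neighbours in stretches set by these same identifiers need not be, so it does not measure their spread. Stretches were also set from the 0 h libraries alone, with identifiers past the rule at 0 h left out. Identifiers past the rule at 36 h, in either direction, were 2.06 times as frequent there as elsewhere (1.86 with at least 20 reads). Of 1000 other placements of the stretches, 5 and 6 reached these ratios. Identifiers past the rule at 36 h but not at 0 h thus gathered in the stretches set at 0 h. They can include differences already present at 0 h, since their 0 h ratio had only to stay under the rule. Whether the difference of any single identifier lasted cannot be read from this, since those past the rule at 0 h were left out. One hypothesis is that identifier numbers follow the genome and the stretches are the substituted segments; that was not tested, and sequence differences that move reads between similar genes stay open.

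Under the 2-fold rule EPlOING identifiers made up 61.3% of the line differences at 0 h and 55.9% at 36 h, but BGIOSGA identifiers were 574 of 603 and 914 of 948 with at least 20 reads. They were also 490 of 782 and 790 of 1242 with FPKM of at least 5, and 3800 of 5451 and 4600 of 6592 with a pseudocount of 0.1 and no filter. Poisson draws without a difference gave 66.1% as many EPlOING calls as observed at 0 h. This lies between the bounds set beforehand for and against counting error as the cause. The draws alone therefore do not tell counting error from real differences for EPlOING identifiers, whose median is 3 reads. Their calls recurred at 36 h no more often than independent lists would, with 110 higher and 142 lower against 125 and 152. Of those higher in DC90 at 0 h, 120 were lower at 36 h, and 103 went the other way.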

How the results depend on the processing

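The filters on recovered reads and the thinning were chosen after the data were seen. Median-of-ratios factors, rescaling to equal FPKM sums and thinning left all 10 counts within 1.5 times of the reported ones. With a pseudocount of 0.1 and no low-value filter, counts of higher and lower identifiers were 7130 and 6740 for chilling in DC90, 7824 lower for chilling in 9311, 2434 and 3017 between lines at 0 h, 3130 and 3462 at 36 h, and 5001 and 4478 for the difference of responses. With FPKM of at least 5 they were 375 and 407 between lines at 0 h, 453 and 789 at 36 h, and 967 and 1127 for the difference of responses. With a 4-fold threshold they were 1185 and 957 in DC90, 1517 and 1150 in 9311, 177 and 212 between lines at 0 h, 219 and 300 at 36 h, and 376 and 427 for the difference of responses. With at least 20 reads they were 268 and 335 between lines at 0 h, 298 and 650 at 36 h, and 782 and 903 for the difference of responses. These filters and thresholds change the counts by their construction, and the low-read EPlOING identifiers make up much of what the filters remove. The fullest window of 50 held 8 identifiers with FPKM of at least 5 and 8 with at least 100 reads, above the 5 reached by shuffles in both cases, and 19 with windows of 100. None of the 20 named ratios changed sign under the 2 settings run for them, but ratios of this size could hardly do so, so this is no check. Of 40 values, 36 stayed within the counting interval or within 0.1, and some intervals are very wide. EPlOING00000025927 at 0 h went from -7.33 to -10.64 with a pseudocount of 0.1, within an interval open on that side. The 4 that moved were EPlOING identifiers in the difference of responses, for which no counting interval was computed. Leaving out a replicate was not possible with 1 library per group, and the alternatives for gene lists were not run because no list member was matched. Pairing the lines within each time, or the times within each line, would leave 1 residual degree of freedom and was not run. Among BGIOSGA identifiers past the rule between lines, the share higher in DC90 was 45.6% at 36 h and 44.9% at 0 h with a pseudocount of 0.1 and no filter. The lower share at 36 h did not hold there, but it held under the other settings. Depth limits the EPlOING identifiers most, since 89.7% have under 20 reads in every library, against 9.01% of the BGIOSGA identifiers.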

Other observations

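The filters on 20 and 100 reads were chosen after the data were seen.

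EPlOING identifiers took a larger share of the libraries after chilling in both lines. Their share of recovered reads was 0.186% at 0 h and 0.263% at 36 h in DC90, and 0.183% and 0.246% in 9311. Of the summed FPKM they took 2.21% and 3.34% in DC90, and 2.31% and 3.23% in 9311. EPlOING identifiers past the 2-fold rule were more often higher than lower after chilling, with 1299 against 575 in DC90 and 1248 against 694 in 9311. With at least 20 reads the counts were 122 against 41 in DC90 and 121 against 48 in 9311.

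BGIOSGA identifiers lower after chilling had shorter coding sequences than the others. In DC90 the median coding length was 816 bases for lower, 1044 for higher and 1083 for the remaining identifiers. In 9311 it was 936, 987 and 1083. Among identifiers with at least 100 reads in either library the medians were 966, 1219.5 and 1209 in DC90 and 1056, 1125 and 1215 in 9311. For identifiers that differed between lines at 0 h the medians were 426 for those higher in DC90 and 678 for those lower, against 1053 for the rest. With at least 100 reads they were 627 for higher, 1053 for lower and 1182 for the rest. In the stretches where line differences gather, 21.6% of identifiers passed the rule for chilling in DC90 and 29.1% in 9311, against 29.0% and 33.5% elsewhere. The stretches were set by differences in these same libraries, so this contrast may partly follow from that choice. Inside them, 8 identifiers were listed at 0 in both DC90 libraries and 10 in both 9311 libraries, and these cannot pass the rule in that line.

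The 10 identifiers with the highest FPKM held 6.59% of the sum in DC90 and 6.30% in 9311 before chilling, and 5.54% and 5.83% after it.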
